A study of Scophthalmus maximus with 15 samples.

How the data were processed

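Liver RNA of 15 juvenile turbot was compared: 7 fish from a control tank and 8 from a tank that received 10% of the water-soluble fraction of heavy fuel oil no. 6 for 3 days, per the labels' protocols. The series title names another grade of fuel oil and styrene as well; the treatment was taken from the protocol. Fish weighed 358 ± 93 g (mean and SD of the whole stock), were acclimatised for 20 days in tanks of 1000 litres and were kept at 16 ± 2 °C, per the labels' protocols. There was 1 tank per treatment. Groups and fish numbers came from the sample titles, and the design text describes separate fish. A protocol note says that a sample was labelled in duplicate as a control; the labels do not tie that note to an array used here. Each array counted as 1 fish, as the titles give it. A duplicate labelling among the arrays was not excluded, since it would differ by more than spot noise. Control replicate 3 was not analysed here.

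From 200 ng of RNA per fish, Cy3-labelled cRNA was made and hybridised to 2 slides, per the labels' protocols and file headers. Slide 1 held 4 control and 4 oil fish, slide 2 held 3 control and 4 oil fish. The authors deposited the scanner output of Agilent Feature Extraction 9.5.3.1, whose processed signal is a linear intensity after background subtraction from negative controls, spatial and multiplicative detrending and surrogate values for dim spots, per the file headers. The mean spot intensity and the median local background intensity were deposited beside it, uncorrected. The authors also deposited a table of 1 signal value per probe and array, whose making is not given in the sources used here. Set against the scanner signals on the log2 scale, its columns correlated at 0.943 for control 1 and at 0.991 to 0.996 for the others. These correlations are across the probes with values above the table's floor. It is therefore a linear scaled signal in the same direction, not centred per probe, with a floor of 0.01 and a scale factor per array that stays unknown. The column of control 1 held 0 values at that floor against 91 to 178 in each other column. Its correlation therefore left out no probe, unlike those of the other columns. Whether the column of control 1 was made in the same way is not known. Its column medians were 0.814, 0.891, 0.872, 0.769, 0.902, 0.899 and 0.879 for controls 1, 2, 4, 5, 6, 7 and 8. For oil fish 1 to 8 they were 0.833, 0.850, 0.912, 0.847, 0.905, 0.860, 0.894 and 0.821. Its identifiers matched the probe numbers of the scanner output for 2715 of the 2716 probes.

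Each array had 13580 spots of 2716 probes and 536 control spots, which were left out. Spots called non-uniform or population outliers were dropped, log2 processed signals of the remaining spots of a probe were averaged, and the array's 75th percentile was subtracted. A probe was tested if at least 0.5 of its usable spots were well above background on at least that share of the arrays of either group; 2535 probes passed and 181 did not. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), and a probe was called at a Benjamini-Hochberg adjusted p below 0.05. Adjusted p-values throughout are limma's. A probe not well above background on every array of a group was given a bound. The bound is the other group's mean against, per array, the higher of the probe's own signal and the lowest signal among probes well above background. The error of that mean is left out, and a p-value beside a bound is that of the fitted change. Single values were compared by exact permutation over the 6435 splits of 15 fish into 7 and 8. The spread between fish was compared as the median over probes of the log2 ratio of SDs, with the same splits of group-centred values.

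The median SD between spots of a probe on an array was 0.11 on the log2 scale, and the median SD between fish of a group 0.35. The steps were tested on simulated arrays with the 2535 probes' own means and SDs, in 5 runs with 200 changed probes each. Of probes changed by 0.5, 1, 1.5 and 2 on the log2 scale, 41.2%, 84.0%, 89.6% and 96.0% were called in the right direction, and 3.96% of all calls were false. The simulated noise was normal and independent between probes. The share recovered also depends on how many probes change. These shares therefore do not give the power of the comparison here, in which 23 probes were called.

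The groups, tests, naming rule and alternative settings were fixed before the data were examined. The naming rule was written for genes with names. It did not say how unnamed probes were to be chosen, and those with the largest changes among called probes were taken. It allowed up to 2 unnamed probes per direction. Because the files give each probe only a number and a sequence, and 0 probe names matched the turbot gene table (assembly ASM2237912v1), only that last part applied. The planned gene lists, cell type markers and the CYP1A check could not be run. Alternatives were median scaling, quantile normalization, normexp background correction (offset 50) with quantile or 75th percentile scaling, the authors' value table, no filter, only probes detected on all 15 arrays, and the median of spots. Others were slide as a block, each slide alone, the fish number as a block, array weights, an intensity trend in eBayes and leaving out each fish. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.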

Results

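Liver RNA of 15 juvenile turbot (Scophthalmus maximus), a marine flatfish, was measured on 1-colour oligonucleotide arrays. Of these fish, 7 had been kept in clean seawater and 8 had been exposed for 3 days to the water-soluble fraction of a heavy fuel oil at 10%. That fraction holds the oil compounds that dissolve in water run over oil-coated beads. Each array carried 2716 probes of 54 to 60 bases, each printed as 5 spots. Between 2309 and 2560 probes per array were well above background, and 2282 probes were so on all 15 arrays. The 75th percentile of the signal lay between 3344 and 7017 intensity units. It was 5482 ± 857 in control fish (SD, n = 7) and 5232 ± 993 in oil fish (SD, n = 8), a difference within the spread between fish (two-sided exact permutation p = 0.624). The number of arrays limited the precision: the median SE of a log2 difference between groups was 0.18. The probes carried no gene name or description, so changes are given by probe and no gene, pathway or cell type is named.

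The design asked which liver transcripts differed after 3 days in oiled water. Of 2535 probes tested, 23 differed between the groups (limma, Benjamini-Hochberg adjusted p below 0.05), which is 0.907% of them. In oil fish 6 of these rose and 17 fell. Probe R1__1875 stood out with the largest rise, 20.1-fold (95% interval 14.2 to 28.3, adjusted p = 1.36e-08), and separated the groups completely. The largest falls were in probes whose signal dropped to the background in nearly all oil fish. Most of the measured liver transcripts changed little: 88.2% of the probes differed by less than 0.5 on the log2 scale, and for 2103 probes (83.0%) the 95% interval excluded a 2-fold change in either direction.

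**Figure D1:**
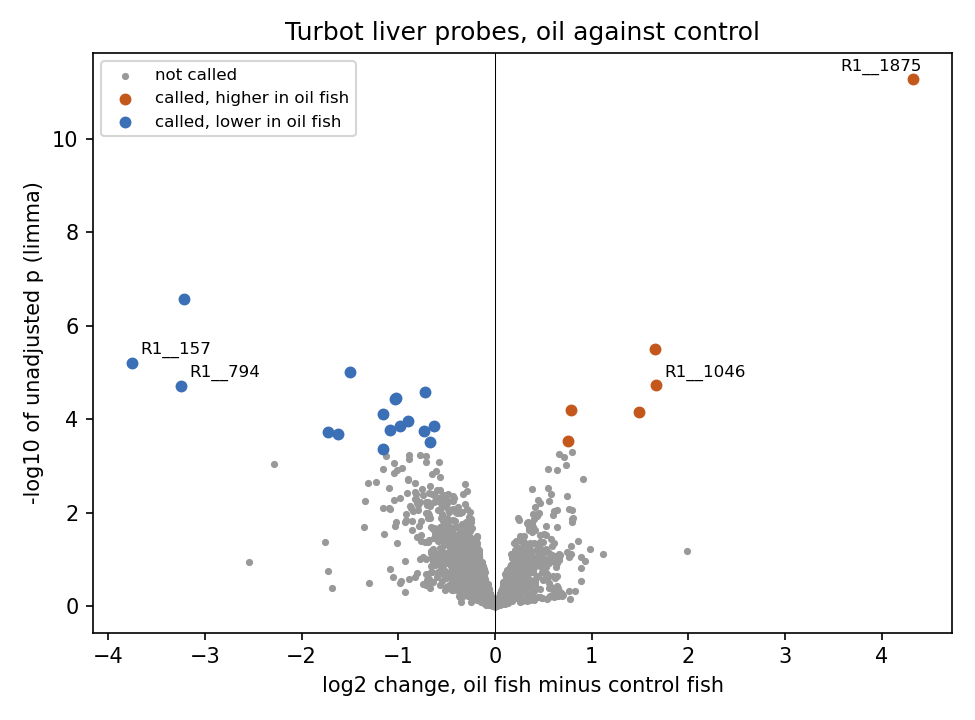
Each point is a probe, placed by its log2 change in oil against control fish (horizontal axis) and by the -log10 of its unadjusted p from limma (vertical axis), over 2535 tested probes. The 6 probes called higher in oil fish are orange, the 17 called lower are blue, and R1__1875 lies apart from all others at 4.33.

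R1__1875 (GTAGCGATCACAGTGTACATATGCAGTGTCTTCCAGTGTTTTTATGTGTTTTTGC) rose by 4.33 on the log2 scale (SE 0.23). Its log2 level relative to the 75th percentile was -5.51 ± 0.63 in control fish (SD, n = 7) and -1.18 ± 0.29 in oil fish (SD, n = 8). The highest control fish stood at -4.90 and the lowest oil fish at -1.59. The probe was well above background in 6 of 7 control fish and in 8 of 8 oil fish. Its rise was 4.45 within slide 1 (adjusted p = 0.00319) and 4.15 within slide 2 (adjusted p = 0.000607), and 4.31 with slide as a block, all from limma. It was called under every alternative setting that tested it.

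R1__1046 (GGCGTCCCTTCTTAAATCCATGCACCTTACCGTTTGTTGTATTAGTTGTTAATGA) rose 3.18-fold (95% interval 2.12 to 4.76, limma adjusted p = 0.00688). Its log2 level was -4.95 ± 0.61 in control fish (SD, n = 7) and -3.28 ± 0.52 in oil fish (SD, n = 8), and every oil fish was above every control fish. The rise was 1.57 on the log2 scale within slide 1, 1.75 within slide 2 and 1.65 with slide as a block (limma adjusted p = 0.467, 0.0956 and 0.00984). The third largest rise was nearly the same size, 1.65 on the log2 scale (SE 0.23, limma adjusted p = 0.00267), also without overlap between the groups. The 4 probes that rose besides R1__1875 and R1__1046 rose by 0.76 to 1.65.

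Falls were ranked by the fitted change, and the order among those with only a bound was not measured. R1__157 (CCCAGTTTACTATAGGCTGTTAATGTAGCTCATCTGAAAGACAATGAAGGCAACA) was at least 3.44-fold lower in oil fish (limma adjusted p = 0.00387). It was not well above background in any of the 8 oil fish and was well above it in 5 of 7 control fish, so its change has only a bound. The bound sets the control mean against the lowest signal that was well above background on each oil array, or the probe's own where higher. It leaves out the error of the control mean, and the p-value is that of the fitted change. The measured log2 means were -6.27 ± 1.66 in control fish (SD, n = 7) and -10.03 ± 0.45 in oil fish (SD, n = 8). R1__794 (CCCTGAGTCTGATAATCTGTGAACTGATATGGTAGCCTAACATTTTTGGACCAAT) fell by 3.25 on the log2 scale (SE 0.54, limma adjusted p = 0.00688), from -5.85 ± 1.47 (SD, n = 7) to -9.10 ± 0.71 (SD, n = 8). It was well above background in 6 of 7 control fish and 1 of 8 oil fish, so the size of this fall rests on dim signals. The probe with the third largest fall, like that with the third largest rise singled out after its values were seen, was well above background in 6 of 7 control fish and in 0 of 8 oil fish. It was at least 3.69-fold lower in oil fish (limma adjusted p = 0.000344).

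**Figure D2:**
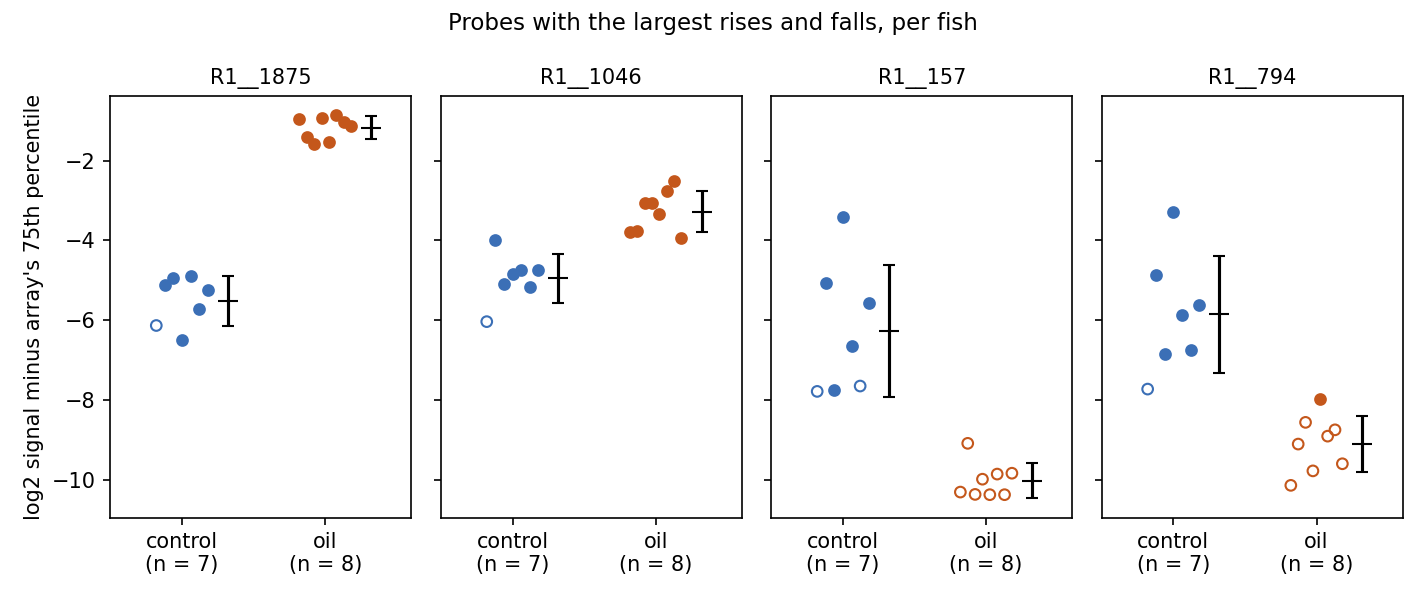
Each point is a fish's log2 signal of a probe minus the array's 75th percentile, for 7 control fish (blue) and 8 oil fish (orange); open points were not well above background, and bars give the mean and SD. In R1__1875, R1__1046, R1__157 and R1__794 no oil fish overlaps a control fish.

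Within slide 1, neither R1__157 nor R1__794 was well above background in any of the 4 oil fish. The bounds there were 4.10-fold for R1__157 and 5.14-fold for R1__794. They lean on control 5, the highest control fish at -3.42 and -3.30. Neither fitted log2 change, -3.93 and -3.72, was called within slide 1 (limma adjusted p = 0.376 for each). Within slide 2, the bound for R1__157 was 2.72-fold (fitted log2 change -3.49, limma adjusted p = 0.031). R1__794, well above background in 1 of 4 oil fish of slide 2, had a fitted log2 difference of -2.73 (limma adjusted p = 0.0423). With slide as a block both were called (limma adjusted p = 0.00593 and 0.00984). Neither probe was called after quantile normalization, where the fitted log2 changes were -3.07 and -2.78 (limma adjusted p = 0.0578 and 0.0528), or in the authors' value table (limma adjusted p = 0.217 for each). Nor was either called with the normexp background settings, whose offset itself shrinks differences between dim signals; with the 75th percentile the fitted changes there were -1.34 and -1.31 (limma adjusted p = 0.125 and 0.0822). The third was not called with normexp either (limma adjusted p = 0.0631 and 0.0883). It was, however, called after quantile normalization, in the authors' value table and whichever single fish was left out.

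Besides the 3 probes with the largest falls, 14 fell, with log2 changes between -1.73 and -0.63. A log2 change of at least 1 was reached by 15 of the 23 called probes, of which 4 rose and 11 fell. In 9 of the 23 (3 that rose, 6 that fell) no oil fish overlapped a control fish. Over all tested probes 10 did so, or 0.394%, where chance gives 0.0311%. At an unadjusted p under 0.05 there were 306 probes, 74 higher and 232 lower in oil fish, against 126.75 expected with no effect among independent probes. Of 99 other groupings of the same fish into 7 and 8, 5 gave as many or more, up to 525, so this count is within what arbitrary groupings give.

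Slide 1 alone called 1 probe, which was among the 23, slide 2 alone called 17, of which 4 were, and with slide as a block 26 were called, of which 22 were. Without control 5, 84 probes were called (12 rose, 72 fell), and without oil 1, 15. Median scaling gave 12 that rose and 15 that fell, quantile normalization 9 and 10, and the table of the authors' values 9 and 6. Each treatment had its own tank, so tank and exposure cannot be told apart.

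Whether oil fish varied more or less among themselves than control fish was also asked. The SD among oil fish was 0.799 of that among control fish at the median probe, a log2 ratio of -0.32 (two-sided exact permutation p = 0.245 over 6435 splits). The control SD was the higher in 1705 of the 2535 probes (67.3%). The ratio rested on 1 fish: without control 5 it was 0.02 (exact permutation p = 0.922). The first principal component, with 22.4% of the variance between fish, showed no detectable difference between the groups (exact permutation p = 0.772), nor did the second, with 18.4% (exact permutation p = 0.641). The next pair, with 14.1% and 10.5%, had unadjusted exact permutation p = 0.0176 and 0.0216 over the 4 components examined. No probe was called between the 2 slides with limma (35 at an unadjusted p under 0.05).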

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

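The test of other groupings was chosen in advance; the tests of scaling, of the control 1 array and of groupings for unadjusted p were chosen after the calls were seen. Among 22 sets of values from a group of fish, 4 had a fish far from the others of its group, where about 1 in 20 sets, or 1.1, is so by chance. On the array of control 1, 7.58% of spots were called non-uniform, against at most 0.361% in the other control fish, and the median SD between spots was 0.17 on the log2 scale, against at most 0.08. Control 5 lay farthest from its own group, with a median absolute log2 deviation of 0.50 against 0.29 for the next control fish. For R1__157, oil 2 stood at -9.09 on the log2 scale against -9.84 for the next oil fish, both not well above background. Apart from these 4 sets, spots called population outliers, which were dropped, were most frequent on the array of oil 2, at 5.48%. Control 1 followed with 4.01%. Without oil 2, 24 probes were called.

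The 23 probes called included 17 that fell. Of 100 splits of the 15 fish into 7 and 8, only 1, the real grouping, gave as many calls, and the highest of the others gave 1. For changes of at least 1 on the log2 scale the real grouping gave 15 and the highest other 1, again 1 of 100. Arbitrary grouping of the fish is therefore unlikely for both counts, but the 100 splits, drawn from 6435, cannot exclude it. Differences between the tanks were not tested by these splits. For the 306 probes at an unadjusted p under 0.05 arbitrary grouping stays possible, since 6 of the 100 splits, the real one included, gave as many, the highest other 525. The control 1 array does not account for the excess of falls, since without it 78.6% of the calls fell, against 73.9% with all fish. Whether scaling does stays open: the share that fell was 55.6% with median scaling (12 rose, 15 fell) and 52.6% with quantile normalization (9 and 10), both still above 50%, and the 42.9% after normexp and quantile normalization changed the background step as well. The exposure, and the tank it came with, also stay open.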

How the results depend on the processing

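The settings without control 1 and control 5 together, with the authors' values without control 1 and with the mean of the co-varying probes as a covariate were chosen after seeing the data. Of the 23 calls, 4 held in all 14 alternatives other than the single slides, the replicate block and the single left-out fish. Among these 14, the setting restricted to probes detected on all arrays tested only 15 of the 23. Each of the 23 called probes kept its direction under every one of the 32 alternatives that tested it, which reuse the fish the calls came from. R1__1875 was called in all that tested it, with log2 changes of 3.40 to 4.45 and adjusted p from 2.83e-11 to 0.00319. R1__1046 was not called within either slide or with the replicate block, and R1__157 and R1__794 each lost their call in 6, among which no setting left out a single fish from the main processing. The 4 probes did not enter the setting restricted to probes detected on all arrays.

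Against 23 called (6 rose, 17 fell, 15 with a log2 change of at least 1), quantile normalization gave 10 that fell and 8 of at least 1. Normexp with quantile normalization gave 14 called, 6 fell, 4 of at least 1; normexp with the 75th percentile 15, 9 and 6; the values deposited by the authors 15, 6 and 6 (11 fell without control 1); only probes detected on all arrays 14, 10 and 7. Median scaling gave 12 that rose. Slide 1 alone gave 1 called, which rose, 0 fell and 1 of at least 1, with 4 fish per group and 132 probes at an unadjusted p under 0.05; slide 2 alone gave 2 that rose. Array weights gave 96 called, 15 rose, 81 fell, 33 of at least 1. Without control 1 and control 5 there were 95 called, 10 rose, 85 fell, 40 of at least 1. Leaving out each fish in turn gave 15 to 84 called, 5 to 12 rose, 10 to 72 fell and 11 to 32 of at least 1. The highest values, 84, 72 and 32, came without control 5, the fish farthest from its group; without control 2, 10 fell, and without oil 1, 10 of 15 fell. Of the 23 calls, 14 were kept whichever fish was left out. Otherwise the cause was not tested. The log2 ratio of SDs was 0.12 without control 1 and control 5, and -0.39 to 0.02 over single left-out fish (exact permutation p = 0.0876 to 0.922), with 0.0152 without control replicate 5, where the sign turned. No pairing by fish number was seen: deviations of same-numbered fish correlated at -0.47 to 0.20 over 7 pairs, and 0 of 7 were closest to their own number. So few pairs, without a test, cannot exclude a pairing. With the replicate block 12 probes were called, 3 rose and 9 fell. Signals near background give bounds only, as for 2 called probes. The gene lists, cell type markers and CYP1A were not run because the probes have no gene names.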

Other observations

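All tests in this part were chosen after the patterns were seen. Apart from the comparison of the groups, 124 probes (4.89% of those tested) had an SD between fish over 1 on the log2 scale, against a median of 0.35. In 44 probes the range over the 15 fish exceeded 6 on the log2 scale, and 30 of these, picked by clustering on their correlation across fish, rose and fell together. Their mean level was lowest in control 2, at -5.37, and highest in oil 3, at 3.65. That range of 9.02 rested on control 2, without which it was 5.11. None of the 30 was called between the groups.

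The 30 co-varying probes had a mean log2 level of 0.11 ± 2.67 in control fish (SD, n = 7) and 0.60 ± 1.67 in oil fish (SD, n = 8; exact permutation p = 0.701), but the difference of oil from control fish was 2.88 on slide 1 and -2.30 on slide 2, where all 3 control fish lay above all 4 oil fish (exact permutation p = 0.171 and 0.0286, unadjusted). Without control 2 the difference on slide 1 was 1.47. The groups held 1.45% of the variance of the mean level and the slides 0.0849%, but the 4 combinations of group and slide held 40.6%, where 21.4% is expected by chance. Without control 2 the combinations held 51.4%. Exposure and slide, alone or together, do not account for all of the variation of the mean level, of which their 4 combinations held 40.6%. Among fish of the same group and slide the members' median SD was 5.60 times that of all other probes (4.02 times without control 2). The members were picked for a wide range over these same fish, which itself raises that ratio. A part played by exposure and slide together stays open. A single source of these transcripts, present in each piece of liver in a different amount, stays open. The same 30 probes were picked on slide 1 alone. That slide holds both the lowest and the highest fish, so this pick was not independent of the first. In the 7 fish of slide 2 the mean of the other members took their median SD from 1.42 to 0.43, or 1.43 times that of all other probes. With group means removed it took the SD only from 0.69 to 0.38. Joint regulation was not tested, and which transcripts and cells these are stays open because the probes have no gene names.

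The 3 probes with the largest falls, R1__157, R1__794 and another chosen after its values were seen, ranked the 7 control fish in the identical order. Pearson's r among the control fish was 0.97, 0.94 and 0.99 and Spearman's rho 1 for each pair (exact permutation p = 0.000198 for r and 0.000397 for rho; adjusted over 9 correlations 0.000446 and 0.000893). Without the 2 fish farthest from the median r was 0.87, 0.76 and 0.96. In the 4 control fish of slide 1 it was 0.98, 0.98 and 1.00, and slide 2, with 3, held too few for a value of its own. In the 8 oil fish, where nearly all these signals were not well above background, R1__157 correlated with the other 2 at -0.23 and -0.13 (rho -0.52 and -0.19, exact permutation p = 0.596 and 0.730 for r and 0.197 and 0.665 for rho). R1__794 and the unnamed probe correlated in oil fish as well, at 0.96 (rho 0.90, exact permutation p = 0.000322 and 0.00456), although these signals were dim.

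A single control fish does not account for these 3 falls: without control 5, the highest, the smallest fitted fall was -2.82 on the log2 scale and all 3 stayed called (limma adjusted p up to 0.00392). Nor does shared probe sequence, the longest run shared by any 2 of the 3 being 6 bases. Whether the 3 probes measure separate transcripts is not known, because they have no gene names. The normexp background settings cannot decide about noise of signals near background: 0 of the 3 probes were called under both, but the offset of 50 alone would shrink a real fall as much. With the 75th percentile the fitted change of R1__157 was -1.34 (SE 0.37) and that of R1__794 -1.31 (SE 0.33) with normexp, where the offset added to the measured signals, unscaled, gave -1.31 and -1.39. The 3 probes were well above background in 5, 6 and 6 of 7 control fish and in 0, 1 and 0 of 8 oil fish. Their identical order of the control fish argues against noise independent between probes as the source of the signals in control fish. It does not bear on noise shared between probes of an array, which was not tested. The order was close in places: for R1__157, controls 7, 4 and 1 lay at -7.65, -7.75 and -7.79. The size of the falls stays open, since nearly all signals in oil fish were dim. Exposure and tank stay open as well.

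Among the tested probes outside that set, 8 had a gap of 3.28 to 6.70 on the log2 scale between a low and a high set of fish, R1__1875 being 1 of them. In 4 of the 8 a single fish was low, in 3 of these 4 an oil fish. The 2 pairs of probes with identical sequences differed on average by 0.09 and 0.02 on the log2 scale within an array, and at most by 0.87 and 0.05.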
